A study of Homo sapiens with 9 samples.

How the data were processed

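Gene expression was measured in FaDu, an established head and neck squamous carcinoma cell line, on 9 arrays: 3 of cells given a control shRNA, 3 of cells given the ACTL6A hairpin named A07 and 3 of cells given the ACTL6A hairpin named B02. Per the labels' protocols, total RNA was taken 72 hours after lentiviral knockdown and copied into biotin-labelled cRNA from an oligo-dT primer. The labels call the control both a control shRNA and a control vector, give 2 target sequences without tying either to a hairpin name, and do not say whether the 3 replicates of a group were separate cultures. If they were not, the p-values measure only the spread between these samples, which may be technical.

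The deposited values are intensities on a linear scale, 1 per probe set and array, from 2.357 to 16998, in a table of 32321 probe sets. Per the submitters' processing notes the arrays were summarised with RMA in R 2.15.1. RMA usually gives log2 values, so the linear scale was read from the range of the values, and log2 was taken before every test. No background correction or normalization was added, because the array medians already lay between 58.7 and 61.9 on the linear scale. Detection calls were not used here, so a gene with a low level has no stated limit of detection. Genes in the lowest 40% of mean level, below a log2 value of 5.92, are called dim.

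Probe sets were named from the platform annotation given with the table, and symbols were brought up to date through the Entrez gene identifiers of the GRCh38.p14 RefSeq gene table, which matched 19128 probe sets. Of the probe sets, 19158 had 1 gene symbol, 1388 had several and 11775 had none listed. A probe set with several symbols or none named no gene. TP63, the gene of p63, had no probe set of its own under this rule and was not analysed here, like KRT6A and KRT17. Where a gene had more than 1 probe set, the one with the highest mean over the 9 arrays was used, which left 18404 genes. Of the 637 genes with more than 1 probe set, 48 passed the threshold in the mean of both hairpins, and 9 of these had another probe set of opposite sign, none of which (0) passed.

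Linear models were fitted to the log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean per group and all 9 arrays in the fit. The comparisons were A07 against control, B02 against control, the mean of both hairpins against control, and B02 minus A07. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. A gene counted as changed with both hairpins when it passed in both hairpin comparisons with the same sign. The 22 gene lists, with 693 genes of which 45 were not measured here, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated for each list, and fry, were the alternatives. Counts of list members are given over all genes and adjusted over the list alone.

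The gene lists, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named ACTL6A, TP63, YAP1, WWC1, CCN1, CCN2, IVL, KRT5 and KRT14 in every case. It added, among genes changed with both hairpins, the 10 with the highest and the 10 with the lowest mean log2 fold change. For each hairpin it added the 5 highest and 5 lowest genes among those that passed for that hairpin and for B02 minus A07, with the larger change in that hairpin. For each list it added up to 4 members with the largest change among those that passed in the mean of both hairpins, or up to 2 with the smallest p where none passed. Genes outside the rule are marked as chosen after their values were seen.

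The fit was tested on simulated data made from the gene means and spreads of these arrays, with 18404 genes. Of these, 200 were changed alike with both hairpins by set sizes, and a list of 30 others was shifted alike. Each gene was drawn independently, and the share recovered depends on how many genes change, so it may differ in these arrays. Of genes changed by 0.25 on the log2 scale, 23.6% were recovered in the mean of both hairpins and 6% with both hairpins. At a change of 0.5 these shares were 89.4% and 77.2%, and at a change of 1 they were 99.4% and 99.2%. The alternatives were a replicate block, fits on only the arrays compared, quantile normalization, median centring and leaving out dim genes. They also included other rules for several probe sets, all probe sets, other variance models, stricter thresholds and leaving out each array in turn. For the mean of both hairpins, the fit on the arrays compared used every array, with A07 and B02 pooled. A term for each array's 75th percentile and changes to list membership were added after the data were seen. The number of arrays limits the precision: the median residual SD per gene was 0.0960 on the log2 scale, with 6 residual degrees of freedom.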

Results

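ACTL6A encodes an actin-like subunit shared by the BAF and INO80 chromatin remodelling complexes and the TIP60 acetyltransferase complex. The series asked how ACTL6A and p63 act on Hippo-YAP signalling in squamous cell carcinoma. Arrays of FaDu cells with a control shRNA or vector, with ACTL6A hairpin A07 and with ACTL6A hairpin B02 were compared, with 3 arrays in each group. Arrays of 1 group correlated with r between 0.990 and 0.996 across probe sets, which are not independent replicates. At most 6.44% of values were identical in a pair of replicates. The 75th percentile of log2 intensity lay between 7.68 and 7.78, and it was lowest in B02 replicate 3, A07 replicate 1 and control replicate 3. Array B02 replicate 3 also lay farthest from its group mean, at a root mean square deviation of 0.144.

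ACTL6A (probe set 8084067) fell with both hairpins. Its log2 intensity was 8.88 ± 0.07 in control cells, 7.08 ± 0.05 with A07 and 6.85 ± 0.20 with B02 (SD, n = 3 each), or 28.7% and 24.5% of control. The log2 fold changes were -1.80 with A07 (adjusted p = 1.21e-05) and -2.03 with B02 (adjusted p = 3.96e-05), each with a standard error of 0.09. B02 minus A07 was -0.23 (adjusted p = 0.224), so the depth of knockdown did not differ past the threshold. WWC1, which encodes the Hippo regulator KIBRA, rose by a log2 fold change of 0.58 with A07 and 0.27 with B02 (adjusted p = 3.64e-04 and 0.0247). WWC1 was a gene of the study itself, so its rise here is not independent evidence.

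YAP1, the transcriptional coactivator of the Hippo pathway, had log2 fold changes of 0.11 with A07 (adjusted p = 0.229) and -0.19 with B02 (adjusted p = 0.0601). Its level differed between the hairpins, by -0.30 for B02 minus A07 (adjusted p = 0.00694). CCN1 and CCN2, which are widely used YAP target genes, did not pass with either hairpin. CCN1 had log2 fold changes of 0.02 and -0.06 and CCN2 of 0.21 and -0.04, for A07 and B02. KRT5, a basal keratin, fell with A07 (-0.37, adjusted p = 0.00235) and had a log2 fold change of 0.01 with B02. The difference for KRT5, 0.37, passed as well (adjusted p = 0.00283). KRT14, its basal partner keratin, had log2 fold changes of -0.07 and -0.05. The differentiation gene IVL, which was dim, had log2 fold changes of -0.08 and -0.19, and neither gene passed.

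**Figure D1:**
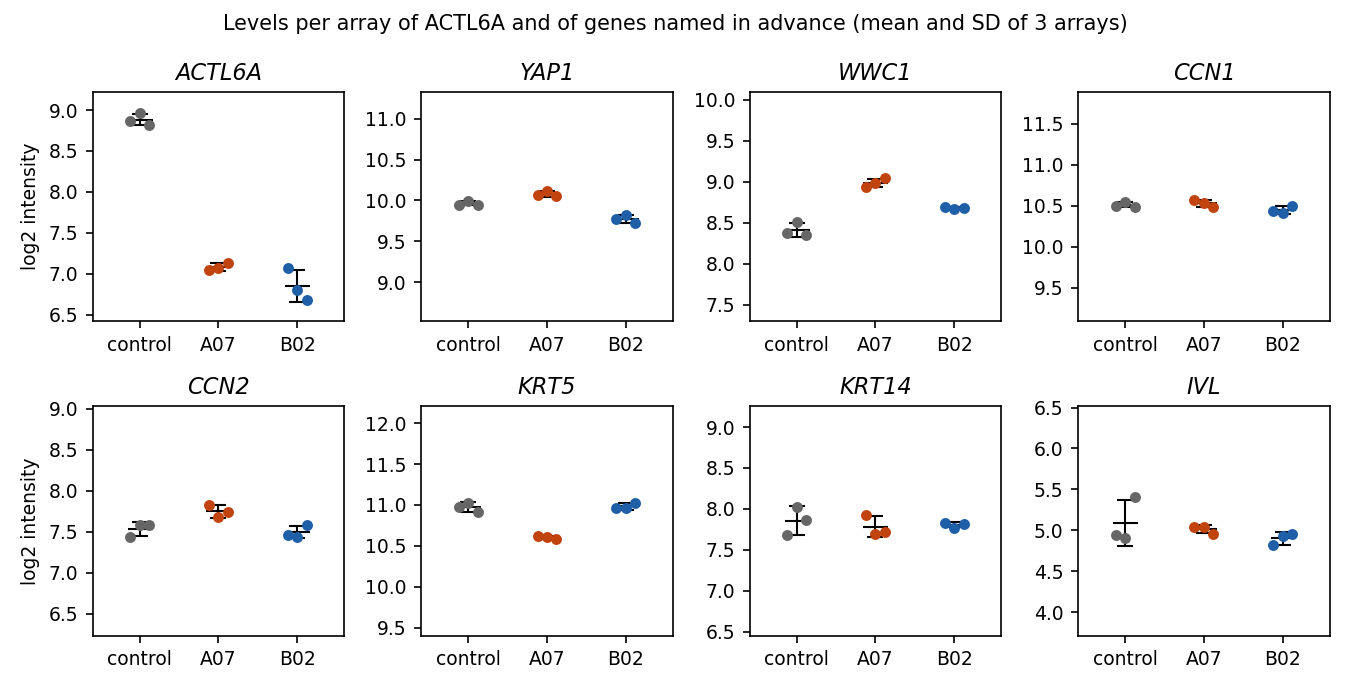
Log2 intensity (vertical axes, each spanning the same number of log2 units) of 8 genes in the 9 arrays. Dots are arrays and black bars are the mean and SD of 3 arrays per group; ACTL6A was lower with both hairpins, and WWC1 was higher with both.

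In the mean of both hairpins, 1348 of 18404 genes changed, 874 up and 474 down. With both hairpins in the same direction, 460 genes changed, 357 up and 103 down. The genes that rose most were led by interferon-induced genes: IFI44L rose by a log2 fold change of 1.75 ± 0.11 (standard error, adjusted p = 5.36e-05), IFI27 by 1.30 ± 0.06 and IFI6 by 1.13 ± 0.05. CCDC80, which encodes a secreted matrix protein, rose by 1.22 ± 0.06, and MGAT4A, an N-glycan branching enzyme, by 1.13 ± 0.05. ENPP5 rose by 1.05, PDCD1LG2, which encodes a ligand of the receptor PD-1, by 1.04, and ABCA12, a keratinocyte lipid transporter, by 1.02. PSG4, a pregnancy-specific glycoprotein gene, rose by 1.01, although near-identical relatives of this family can share probe signal. PPIC, which encodes a cyclophilin, rose by 1.00. The count of 1348 fell to 882 without control replicate 3, 878 without A07 replicate 2, 851 without A07 replicate 3 and 872 without B02 replicate 2. The count of 460 fell to 274 and 273 without A07 replicates 2 and 3, and to 302 and 221 without B02 replicates 1 and 2. In the mean, the genes up fell to 495 without control replicate 3 and 578 without A07 replicate 3, and the genes down to 236 without control replicate 2, to 314, 277 and 273 without A07 replicates 1, 2 and 3, and to 264 without B02 replicate 2. With both hairpins, the genes up fell to 205 without control replicate 3, to 215 and 213 without A07 replicates 2 and 3, and to 230 and 185 without B02 replicates 1 and 2. The genes down fell to 48 without control replicate 2, to 68, 59 and 60 without A07 replicates 1, 2 and 3, and to 36 without B02 replicate 2.

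Below ACTL6A, the largest falls with both hairpins were in IL24, a cytokine gene that was dim here, at -1.40 ± 0.09 (adjusted p = 4.7e-05), and GOLT1B, a Golgi vesicle transport gene, at -0.98 ± 0.09. SEC23B, a coat protein of vesicles leaving the endoplasmic reticulum, fell by 0.72. EXTL2, a glycosyltransferase gene, fell by 0.66 and POMK, an O-mannose kinase gene, by 0.64. The fatty acid elongase gene ELOVL5 fell by 0.60, the messenger RNA decapping gene DCP1A by 0.57, the selenoprotein gene SELENOT by 0.56 and the corepressor gene RCOR1 by 0.53. IL24 had mean log2 levels of 6.68 in control, 4.98 with A07 and 5.58 with B02, the latter pair in the dim range and not shown to lie above background, so its size of change is uncertain.

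Interferon-stimulated genes rose as a group with both hairpins. Of 41 measured members, 27 rose and 0 fell in the mean of both hairpins (32 and 1 adjusted over the list alone). Against control 24 rose with A07 and 24 with B02, and 18 of these rose with both. MX1, an antiviral GTPase, rose by 0.99 (adjusted p = 5.04e-04), next to the larger rises of IFI44L, IFI27 and IFI6. The list median was 0.44 (camera adjusted p = 9.45e-28; adjusted p = 0.106 with an estimated correlation). The list mean was 0.48 ± 0.04 above control with A07 and 0.48 ± 0.11 with B02 (SD, n = 3 each). Other members did not pass: ISG15 had log2 fold changes of 0.05 and -0.04 and IRF7 of -0.09 and -0.08, both chosen after their values were seen.

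YAP and TAZ target genes rose in the mean of both hairpins, with 12 of 22 up and 0 down, the same counts adjusted over the list alone. Besides CCDC80, TGFB2, a growth factor gene, rose by 0.71, NT5E, which encodes an ecto-nucleotidase, by 0.71, and IGFBP3, a binding protein of insulin-like growth factors, by 0.70. The list median was 0.20 (camera adjusted p = 1.1e-11; adjusted p = 0.106 with an estimated correlation). Of the 22 lists 11 were called in the mean, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05 and fry called 9. Of the 34 Hippo pathway components, 6 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.00106; adjusted p = 0.322 with an estimated correlation). These lists share 3 genes, PTPN14 among them. The Hippo list was called with A07 (median 0.12, camera adjusted p = 1.22e-05; adjusted p = 0.142 with an estimated correlation) and not with B02 (median 0.02, camera adjusted p = 0.265). The cadherin-family genes FAT1 and FAT4 rose by 0.52 and 0.44, and the phosphatase gene PTPN14 by 0.33, next to WWC1 at 0.42.

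Cholesterol synthesis genes rose, with 6 of 20 up and 0 down (8 and 0 adjusted over the list alone). MSMO1 rose by 0.47, HMGCS1 by 0.41, SQLE by 0.40 and SC5D by 0.38, all of them enzymes of the pathway (camera adjusted p = 1.18e-04; adjusted p = 0.272 with an estimated correlation). The cholesterol list was called with A07 (median 0.15, camera adjusted p = 8.62e-07; adjusted p = 0.0941 with an estimated correlation) and not with B02 (median 0.02, camera adjusted p = 0.073). Among autophagy and lysosome genes 7 of 26 rose and 0 fell (9 and 0 adjusted over the list alone), including the lysosomal cholesterol transporter gene NPC1 at 0.45, the cathepsin genes CTSA at 0.34 and CTSL at 0.33, and WIPI1 at 0.33 (camera adjusted p = 5.2e-04; adjusted p = 0.322 with an estimated correlation). The count of 7 fell to 3 without control replicate 3. Among p53 target genes 5 of 27 rose (3 without control replicate 2 or 3) and 0 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.322 with an estimated correlation). The p53 list was called with A07 (camera adjusted p = 4e-05; adjusted p = 0.133 with an estimated correlation) and not with B02 (camera adjusted p = 0.265). PLK2 rose by 0.47, SESN1 by 0.39 and CCNG1 by 0.38, and TRIM22, which was dim and is also on the interferon list, by 0.63.

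Basal keratinocyte and p63-linked genes had 4 of 22 up and 1 down (7 and 1 adjusted over the list alone; camera adjusted p = 0.00106). Its adjusted p was 0.328 with an estimated correlation. The count of 4 fell to 2 without control replicate 1, A07 replicate 1 or B02 replicate 1 or 2, and to 1 without control replicate 3 or A07 replicate 2 or 3. The single fall passed only in the full data and without control replicate 3 or B02 replicate 3. The growth factor receptor gene FGFR2 rose by 0.67, CDH3 by 0.25, DST by 0.24 and ITGA6, a hemidesmosomal integrin gene, by 0.24. Squamous differentiation genes had 7 of 51 up and 1 down, the same counts adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.038; adjusted p = 0.391 with an estimated correlation). KRT4 rose by 0.49, ZNF750, a regulator of epidermal differentiation, by 0.45, and the junction genes PPL and DSC2 by 0.44 each. The squamous list was not called with A07 or B02 alone (camera adjusted p = 0.18 and 0.073). Of its 51 members 26 were dim, and its call in the mean ended without control replicate 1 or 2, A07 replicate 1 or B02 replicate 3, with a highest adjusted p of 0.268. The count of 7 fell to 4 without any 1 control array or without A07 replicate 3.

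The unfolded protein and ATF4 stress list had 11 of 32 members up and 2 down (13 and 3 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 4.64e-04; adjusted p = 0.328 with an estimated correlation). The hairpins went opposite ways, with list medians of 0.34 with A07 and -0.12 with B02. VLDLR, a lipoprotein receptor gene, rose by 0.58 and DNAJC3 and SDF2L1 by 0.39 and 0.32, while SHMT2 fell by 0.36. The count of 11 fell to 6 without control replicate 1 and 7 without control replicate 3.

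MYC and ribosome biogenesis genes fell, with 6 of 34 down and 0 up (14 and 0 adjusted over the list alone). RRP1B fell by 0.49, DKC1, which encodes the pseudouridine synthase dyskerin, by 0.26, WDR74 by 0.22 and TCOF1 by 0.21. The list median was -0.13 (camera adjusted p = 8.62e-09; adjusted p = 0.322 with an estimated correlation). The count of 6 fell to 3 without control replicate 1 or 2, A07 replicate 2 or B02 replicate 2. DNA replication genes had a median of -0.04 (camera adjusted p = 0.0379; adjusted p = 0.835 with an estimated correlation), and 0 of 44 members passed on either count in limma, with 8 at an unadjusted p under 0.05. Their log2 fold changes included -0.18 for RFC4 and -0.16 for RFC5, which encode subunits of the clamp loader. The DNA replication list was not called with A07 or B02 alone (camera adjusted p = 0.055 and 0.125), and its call in the mean also ended without control replicate 1 or 2, A07 replicate 1 or B02 replicate 3.

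The other lists had no camera call in the mean of both hairpins, with adjusted p between 0.141 and 0.881. Member counts of 3 or fewer in the mean moved by at most 2 where leaving out 1 array moved them by over 1.5 times. Among 29 BAF subunits 1 rose, PBRM1 by 0.24, and 1 fell, BCL7C by 0.29 (1 and 2 adjusted over the list alone; camera adjusted p = 0.784). Among 27 INO80 and TIP60 subunits 0 passed on either count in limma and 6 had an unadjusted p under 0.05, with log2 fold changes of -0.16 for MRGBP and 0.15 for INO80D. Of 49 mitosis genes 3 rose and 2 fell (3 and 3 adjusted over the list alone). NDC80 rose by 0.35 and ANLN by 0.23, while CDC20 fell by 0.31 and BIRC5 by 0.30. Of 42 neighbours of ACTL6A on chromosome arm 3q, 3 rose and 2 fell (3 and 3 adjusted over the list alone), with rises of 0.81 for LAMP3, which is also on the interferon list, and 0.79 for PLD1, and falls of 0.57 for TERC, the telomerase RNA, and 0.35 for TFRC. The median of this list was -0.04 and its mean 0.01.

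Inflammatory genes of the NF-kB list had 5 of 31 up and 1 down (7 and 3 adjusted over the list alone), with a median of -0.02 and a mean of 0.04. The chemokine genes CCL5 and CCL20 rose by 0.77 and 0.69, LCN2 by 0.40 and NFKB2 by 0.36. Mesenchymal genes had 4 of 31 up and 2 down (6 and 3 adjusted over the list alone), with a median of -0.01 and a mean of 0.05. ITGA5 rose by 0.63, FSTL1 by 0.45 and CDH2, which encodes N-cadherin, by 0.39, and the dim gene SNAI1 fell by 0.33. Hypoxia and glycolysis genes had 3 of 29 up and 1 down (8 and 8 adjusted over the list alone), with P4HA2 up by 0.43, INSIG2 by 0.33 and ERO1A by 0.21, and ENO1 down by 0.21. NRF2 target genes had 0 of 25 up and 2 down on both counts, UGDH by 0.37 and CBR1 by 0.25. Neither passed with B02: the log2 fold changes with A07 and B02 were -0.69 and -0.05 for UGDH and -0.37 and -0.12 for CBR1.

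Some other genes that passed in the mean passed with A07 and not with B02. With A07 and B02, the log2 fold changes were 1.22 and 0.21 for TGFB2, 1.05 and 0.32 for CCL20, 0.71 and 0.06 for CDH2, 0.72 and 0.21 for PLK2, and 0.60 and 0.16 for CCNG1. They were 0.46 and 0.20 for PTPN14, 0.56 and 0.10 for INSIG2, -0.84 and -0.29 for TERC, -0.60 and -0.10 for TFRC, and -0.48 and -0.04 for DKC1. KRT4, PBRM1, CDC20 and DST passed with B02 and not with A07, at 0.35 and 0.62, 0.17 and 0.31, -0.23 and -0.39, and 0.14 and 0.34. CTSL, WDR74 and TRIM22 also passed with B02 only, and CDH3, ENO1, NDC80, BIRC5, SDF2L1, TCOF1 and SNAI1 with A07 only. ITGA6 and ZNF750 passed in the mean but with neither hairpin alone.

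Markers of other cell types had no camera call. Of 17 fibroblast markers, 13 of them dim, 0 passed on either count in limma and 0 had an unadjusted p under 0.05, and the log2 fold changes of DPT and MFAP5 were -0.10 and -0.18. Of 18 leukocyte and endothelial markers, 14 of them dim, CDH5 alone passed on either count, with a rise of 0.60. The 14 housekeeping genes, the control list, had 1 fall on both counts, that of TFRC, in the mean of both hairpins. The list mean there was -0.02, which turned to 0.00279 after quantile normalization. That mean joins opposite values, -0.0777 with A07 and 0.0422 with B02. Camera called neither, while fry called A07 (adjusted p = 0.00555). B02 minus A07 was 0.12 (camera adjusted p = 0.00748, and 0.24 with an estimated correlation).

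**Figure D2:**
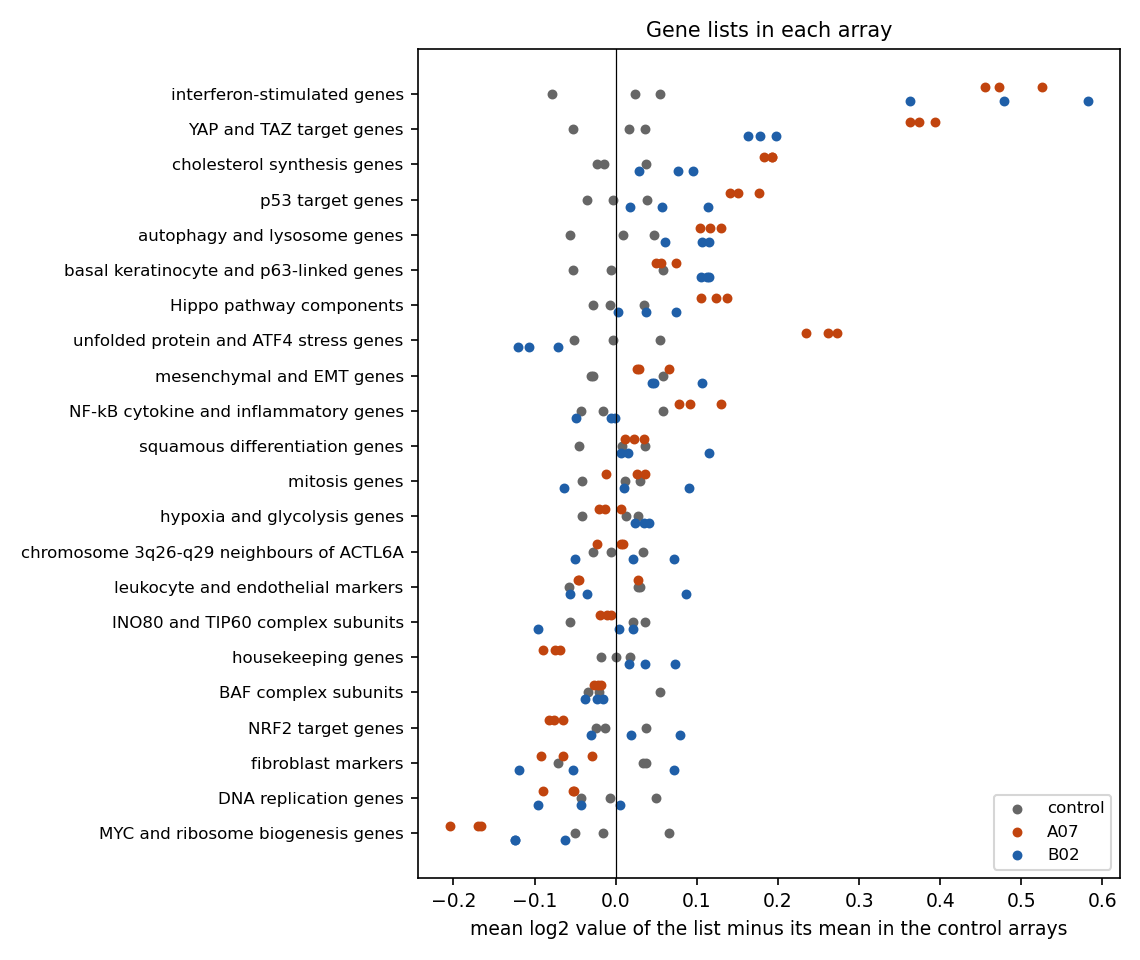
Mean log2 value of each of the 22 gene lists in each array minus its mean in the 3 control arrays (horizontal axis), by group. Each dot is 1 array; the interferon-stimulated list lay between 0.363 and 0.582 in the 6 knockdown arrays, and the unfolded protein and ATF4 list lay above control with A07 and below 0 with B02.

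With hairpin A07 alone, 1489 genes changed against control, 873 up and 616 down. Among genes with the larger effect in A07, the chemokine gene CCL5 rose 2.83-fold (adjusted p = 1.22e-05), and its log2 fold change with B02 was 0.04. IFI27 rose by 1.49, ABCA12 by 1.38 and MACC1, a regulator of the MET receptor gene, by 1.35. IL24, whose size of change is uncertain because it was dim with A07, fell by 1.70, RAB31, a small GTPase gene, by 0.89, FSCN1, which encodes an actin-bundling protein, by 0.87, B3GNT5, a glycosyltransferase gene, by 0.86 and POLR3G, a subunit of RNA polymerase III, by 0.86. CD24, a surface glycoprotein gene, had mean log2 levels of 3.20 in control and 4.99 with A07, both in the dim range and not shown to lie above background, so its size of change is uncertain. The count of 1489 fell to 847 and 842 without A07 replicates 2 and 3. Without these the genes up fell to 527 and 509. The genes down fell to 394 without control replicate 2 and to 372, 320 and 333 without A07 replicates 1, 2 and 3.

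Of the 22 lists 10 were called with A07, 9 up and 1 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.0941, 6 lists had an unadjusted p under 0.05 and fry called 11. The interferon list had 24 members up and 2 down of 41 (28 and 2 adjusted over the list alone), and the YAP and TAZ list 13 up of 22 (16 adjusted over the list alone). The unfolded protein and ATF4 list had 20 of 32 members up and 1 down (20 and 2 adjusted over the list alone), with a median of 0.34. Its camera adjusted p was 3.22e-14, and its adjusted p was 0.0941 with an estimated correlation. The count of 20 fell to 13 without A07 replicate 2. VLDLR rose by 0.85, and the endoplasmic reticulum chaperone genes DNAJC3 and SDF2L1 by 0.55 and 0.51, while SHMT2, which encodes a mitochondrial enzyme of folate metabolism, fell by 0.43. The NF-kB list was called up with A07 (camera adjusted p = 0.0395; adjusted p = 0.347 with an estimated correlation), a call that ended without control replicate 1, A07 replicate 3 or B02 replicate 1, with a highest adjusted p of 0.071. The call of the basal list with A07 (camera adjusted p = 0.0148; adjusted p = 0.485 with an estimated correlation) ended without control replicate 3, at an adjusted p of 0.0573.

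With hairpin B02 alone, 986 genes changed against control, 661 up and 325 down. Among genes with the larger effect in B02, CP, which encodes the copper protein ceruloplasmin, rose by 1.25 ± 0.10 (standard error, adjusted p = 2.43e-04). GPNMB, a membrane glycoprotein gene, rose by 0.95, MANSC1 by 0.85, MMP12, which encodes macrophage elastase, by 0.84 and AASS, an enzyme of lysine breakdown, by 0.78. GOLT1B fell by 1.23, LYRM7, a mitochondrial assembly factor gene, by 0.95, PPP1CA, a catalytic subunit of protein phosphatase 1, by 0.93, PABPC4, a poly(A)-binding protein gene, by 0.88 and POMK by 0.87. LYRM7 had a mean log2 level of 5.74 with B02, in the dim range and not shown to lie above background, so its size of change is uncertain. The count of 986 fell to 637 and 644 without control replicates 1 and 2, to 603 and 424 without B02 replicates 1 and 2, and rose to 1522 without B02 replicate 3. The genes up fell to 438 and 392 without control replicates 1 and 3 and to 365 and 301 without B02 replicates 1 and 2, and rose to 1070 without B02 replicate 3. The genes down fell to 199 and 154 without control replicates 1 and 2, to 210 without A07 replicate 3 and to 123 without B02 replicate 2.

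Of the 22 lists 6 were called with B02, 4 up and 2 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.241, 1 list had an unadjusted p under 0.05 and fry called 3. The interferon list had 24 of 41 members up and 0 down (32 and 0 adjusted over the list alone), and the YAP and TAZ list 5 of 22 up (9 adjusted over the list alone; adjusted p = 0.603 with an estimated correlation). The unfolded protein and ATF4 list had 2 members up and 7 down of 32 (4 and 11 adjusted over the list alone), with a median of -0.12. Its camera adjusted p was 0.0148, and its adjusted p was 0.678 with an estimated correlation. This call ended without control replicate 1, at an adjusted p of 0.0587, and fry did not call the list (adjusted p = 0.0771). The count of 7 down fell to 3 without control replicate 1, and to 2 without control replicate 2 or B02 replicate 1 or 2. The YAP and TAZ count of 5 fell to 3 without control replicate 1 or 3, A07 replicate 2 or 3, or B02 replicate 1 or 2.

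The hairpins were compared directly to see which effects went with 1 hairpin. B02 minus A07 differed for 1032 genes, 565 higher and 467 lower with B02. Among them, CCL5 was lower with B02 by a log2 difference of -1.46 (adjusted p = 2.9e-05), as was TGFB2 (-1.01, adjusted p = 2.9e-05), while MMP12 was higher by 1.10 (adjusted p = 6.62e-05) and RAB31 by 1.01. PPP1CA and PABPC4 were lower with B02 by -0.90 and -0.91. Of the 32 members of the unfolded protein and ATF4 list, 20 were lower with B02 and 0 higher (26 and 1 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 1.51e-26; adjusted p = 0.0599 with an estimated correlation). The count of 20 fell to 13 without A07 replicate 2 and 12 without B02 replicate 2. The count of 1032 fell to 623, 556 and 563 without A07 replicates 1, 2 and 3, and to 574 without B02 replicate 2. Without these arrays, in that order, the genes higher with B02 fell to 324, 306, 321 and 312, and the genes lower to 299, 250, 242 and 262.

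The fold changes with A07 and B02 correlated at r = 0.564 across genes, which are not independent replicates, and 70.5% of genes had the same sign. Simulated groups with no effect, measured against shared controls, gave a mean correlation of 0.5 and 66.7% with the same sign. The observed covariance was 0.0161 and the simulated covariance 0.00423, a difference of 0.0119. Lists of calls that were independent would share 31.4 genes up and 10.9 down, against 357 and 103 observed. These expected numbers do not allow for the shared controls. In the simulation a mean of 0.01 genes, and at most 1, passed in the same direction with both hairpins, against 460 observed. Neither hairpin had an effect there, so it cannot say how many calls unrelated hairpin effects would share. The simulation covers only the spread between arrays, so a deviation common to all 3 control arrays was not tested. It also drew each gene independently, while deviations from group means correlated between arrays of different groups from -0.45 to 0.41 across genes. It therefore cannot say how many calls such shared deviations would give.

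**Figure D3:**
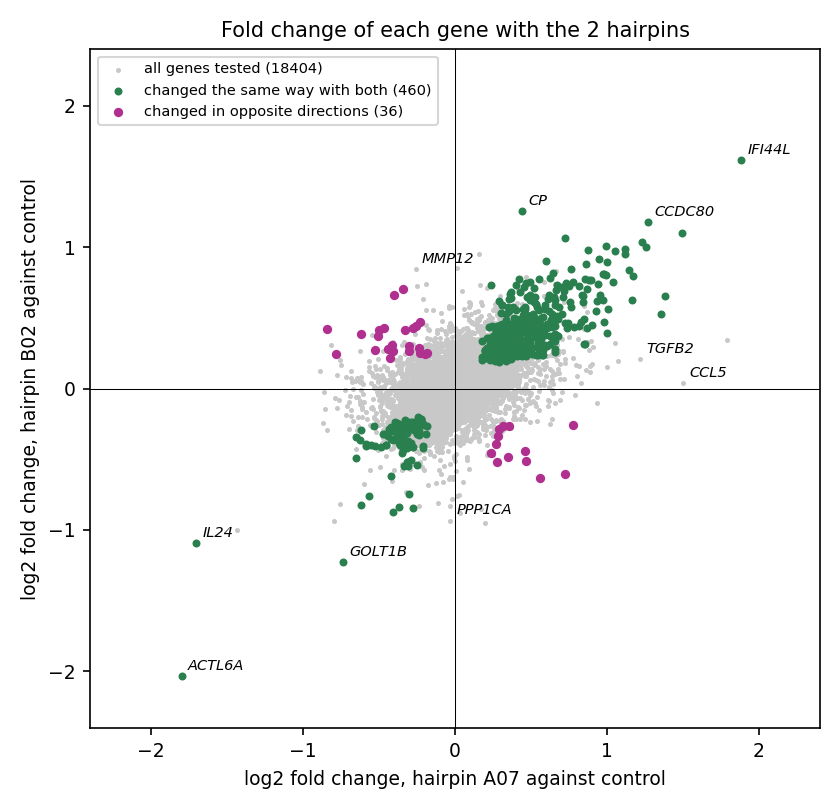
Log2 fold change of each of 18404 genes with hairpin A07 (horizontal axis) and hairpin B02 (vertical axis), each against the same 3 control arrays. Grey dots are all genes, green dots the 460 genes changed in the same direction with both, and purple dots the 36 changed in opposite directions; named genes include ACTL6A at -1.80 and -2.03.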

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

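The tests with the array percentile term, of knockdown depth and of ribosomal protein genes were chosen only after the results were seen, and the other tests in this part were planned.

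The hairpins gave different effects for 1032 genes. All 10 splits of the 6 hairpin arrays into 3 and 3 are too few for a share under 0.05; the real split (1 of 10) gave 1032 genes and the highest of the others gave 0. In addition, 36 genes passed in opposite directions, 13 up with A07 and down with B02 and 23 the reverse. Lists also differed between the hairpins. The list mean of B02 minus A07 was -0.198 for YAP and TAZ target genes, -0.0831 for Hippo pathway components, -0.0938 for p53 target genes, -0.119 for NF-kB inflammatory genes, -0.123 for cholesterol synthesis genes and -0.356 for unfolded protein and ATF4 stress genes. It was 0.0765 for MYC and ribosome biogenesis genes, 0.0968 for NRF2 target genes and 0.12 for housekeeping genes. The housekeeping genes were the control list, and only the YAP and TAZ, cholesterol and stress lists differed by more in size. Differences of the size seen in the other called lists thus also arose in the control list. With an estimated correlation 0 of these 9 lists passed, with adjusted p between 0.0599 and 0.914, while 4 of the 22 lists had an unadjusted p under 0.05 with that correlation and fry called 7. The calls of the MYC and NRF2 lists ended without A07 replicate 1 or B02 replicate 1, with highest adjusted p of 0.164 and 0.0955.

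Signals also lay in probe sets outside the comparisons. Of 11775 probe sets with no gene listed, 127 passed in the mean of both hairpins, and of 1388 with several gene symbols, 32 passed.

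The first pattern is the rise of interferon-stimulated genes with both hairpins. With the 75th percentile of each array in the fit, the lower of the 2 list means was 0.467. The percentile ran from 7.692 to 7.763 in control, 7.722 to 7.753 with A07 and 7.682 to 7.777 with B02. With groups so alike, the term could hardly move a group difference and cannot decide. Quantile normalization, which gives all arrays the same distribution, left list means of 0.495 with A07 and 0.483 with B02. These values argue against the intensity distribution of the arrays as the whole cause. An interferon response to double-stranded RNA or virus stays open, and the values it needs were present, since the lower of the 2 list medians was 0.412 with camera adjusted p = 3.92e-22 for A07 and 3.2e-26 for B02. The call is lost with an estimated correlation (adjusted p = 0.0941 and 0.241), and loss of ACTL6A is a biological explanation that needs the same values, so these arrays do not separate them. Per the labels the control cells received a lentiviral control vector or shRNA, and the labels do not settle whether it carried a hairpin.

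The second pattern is the rise of unfolded protein and ATF4 stress genes with A07 and not with B02 (adjusted p = 0.0599 for the difference with an estimated correlation). The fall with B02 is not firm: its adjusted p was 0.678 with an estimated correlation, and it ended without control replicate 1 (0.0587). It lay in 1 part of the list: the endoplasmic reticulum part had a mean of 0.04 and the 20 other members, called ATF4-linked here, of -0.183. The latter were called (camera adjusted p = 3.32e-06; adjusted p = 0.38 with an estimated correlation). A deeper knockdown with A07 is argued against at the RNA level, since mean ACTL6A was 6.85 with B02 and 7.08 with A07. That difference did not pass in limma (adjusted p = 0.224), so depth in the other direction cannot be weighed. The lowest A07 array lay above the highest B02 array by 0.305 in list mean, which restates the pattern. The intensity distribution as the whole cause is argued against, since the list mean of B02 minus A07 was -0.355 after quantile normalization. With the percentile term, which could hardly move a group difference, that list mean was -0.353. Effects of a hairpin sequence on other transcripts and a difference in ACTL6A protein stay open and were not tested.

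The third pattern is the negative median of ribosomal protein genes with both hairpins, seen in a scan of symbol families made after the data were examined. Families were set by the letters before the first digit of a symbol, so RPS can also hold the RPS6K kinase genes. With an estimated correlation the 4 families together had an unadjusted camera p of 0.0987 with A07, 0.0277 with B02 and 0.0367 in the mean, and each family had an adjusted p of 0.997 with A07 and 0.983 with B02 over 316 families; RPS was not called with A07 (camera adjusted p = 0.333). A shift of all bright genes is argued against, since random lists matched on mean level had a middle median of -0.0163 with A07 and 0.0014 with B02. None (0) of the 10000 lists had a median as low with either hairpin. Their genes were drawn singly and the families were picked after a scan, so this count gives no p-value. Quantile normalization left means over the families of -0.107 with A07 and -0.135 with B02. These values argue against the intensity distribution of the arrays as the whole cause. In the mean of both hairpins, the mean over the families was -0.141 with the percentile term and -0.136 without it. That term could hardly move a group difference. Shared probe signal with pseudogenes was not tested and stays open, as does loss of ACTL6A, the biological explanation the design gives.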

How the results depend on the processing

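The array percentile term and the changes to list membership were chosen after the data were seen; the other alternatives were planned. ACTL6A kept its direction and its call in every alternative run. Among called list shifts 519 values kept direction and call and 64 kept direction without the call. Among named genes 7468 kept both, 447 lost a call and 170 gained one. None (0) of the called values changed sign, and 44 values of uncalled genes did, which was not counted as a reversal. Median centring moved the median of all genes from -0.025 to -0.0088 in the mean of both hairpins.

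Fits on only the arrays compared gave 334 genes for B02, 206 for both hairpins and 1600 for A07, and the cause was not tested. For the mean this setting used every array, with A07 and B02 pooled into a single group, and gave 669. Differences between the hairpins then counted as spread within that group, so this count does not show an effect of leaving arrays out. Leaving out dim genes gave 723 for both hairpins, with fewer genes tested, all probe sets 301, with more tested, and the trended robust variance 693; the cause was not tested for the last. The percentile term gave 1609 genes for B02, 1579 between hairpins and 728 for both; the cause was not tested. Array weights gave 3780 for B02, 2131 for the mean, 6094 between hairpins and 1103 for both. Their estimation stopped before it converged and gave B02 replicate 2 a weight of 24.6, against 0.21 to 1.61 elsewhere. At an adjusted p of 0.01 the counts were 712 for A07, 361 for B02, 539 for the mean, 485 between hairpins and 166 for both. With an absolute log2 fold change of at least 1 they were 23, 10, 13, 17 and 6. Both thresholds are stricter by construction.

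The replicate numbers did not pair the samples: 2 of 9 same-number pairs correlated above 0.1, from -0.35 to 0.41, and 3 arrays correlated best with their own number. The replicate block gave 647 genes for B02 and 301 for both hairpins.

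List calls fell to 0 in all 4 comparisons with an estimated correlation. Fry, which tests the list alone, called 3 lists for B02, against 6 by camera, and 11, 9 and 7 lists for A07, the mean and the difference. Leaving out each array in turn gave 842 to 1918 genes for A07, 424 to 1522 for B02, 851 to 1854 for the mean, 556 to 1183 between hairpins and 221 to 662 for both. The highest of each of these 5 counts came without B02 replicate 3. ACTL6A ranged from -1.97 to -1.87 in the mean, -1.83 to -1.76 with A07 and -2.14 to -1.95 with B02. List calls ranged from 9 to 11 for A07, 5 to 8 for B02, 9 to 11 for the mean and 7 to 9 between hairpins.

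Of 100 drawn splits of the 9 arrays into 3 groups, only the real one (1) gave as many as 1348 genes in the mean, and the highest other gave 953. For both hairpins the real split (1 of 100) gave 460 and the highest other 400. That other split kept the 3 A07 arrays together, but no other drawn split kept all 3 groups whole. Had A07 been the reference, at least 527 genes would have counted. These passed for A07 and for B02 minus A07, with the larger change in A07. The rank of 460 thus rests on the splits drawn and does not exclude chance. The rank of 1348 has the same limit, since the real groups with another reference were not drawn. Its highest other count, 953, came from that same split, with the 3 A07 arrays as the reference. For A07 and for B02 the 10 splits are too few for a share under 0.05; the real splits (1 of 10 each) gave 1489 and 986 genes, and the highest others 0 and 1. Without detection calls, the level below which intensity is background is unknown.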

Other observations

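The scan of symbol families and the split of the stress list were chosen after the data were seen.

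Symbol families that hold the ribosomal protein genes of the cytosol and the mitochondrion had negative medians with both hairpins. A family was the protein-coding symbols with the same letters before the first digit. RPS can therefore also hold the RPS6K kinase genes, which encode no ribosomal proteins, and these were not taken out. Over the 48 MRPL, 25 MRPS, 41 RPL and 35 RPS genes together the median log2 fold change was -0.112 with A07 and -0.142 with B02, and 131 and 138 of them were below 0. Single genes moved little: 20 fell and 1 rose with A07, and 21 fell and 0 rose with B02. Lists of genes drawn singly and matched on mean level had 2.5th percentiles of -0.0425 and -0.0273. Of 316 symbol families 16 passed with camera in the mean of both hairpins, 3 of them up, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. MRPL, the large mitochondrial subunit, had a median of -0.18 (camera adjusted p = 2.01e-11; adjusted p = 0.995 with an estimated correlation), and RPL, the large cytosolic subunit, of -0.12 (camera adjusted p = 4.54e-07; adjusted p = 0.995 with an estimated correlation). With A07 alone RPL had 0 genes down but was called (camera adjusted p = 0.00636), as were MRPL and MRPS. The RPS family, named for the small cytosolic subunit, was not called with A07 (camera adjusted p = 0.333, mean -0.04). With an estimated correlation the families had an adjusted p of 0.997 with A07 and 0.983 with B02. Both MRPL and RPL kept their sign after quantile normalization and after median centring.

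The stress list was split into parts, and the difference between the parts was not tested. The endoplasmic reticulum part held chaperone genes, the transcription factor gene XBP1, and HERPUD1 and SEL1L, which act in protein degradation. All members left over made the part called ATF4-linked. All 12 genes of the endoplasmic reticulum part rose with A07, with a mean of 0.38, and 1 rose and 1 fell with B02, with a mean of 0.04. Of 20 ATF4-linked genes 8 rose and 1 fell with A07, with a mean of 0.183, and 1 rose and 6 fell with B02, with a mean of -0.183. B02 minus A07 passed in camera for both parts with an estimated correlation (adjusted p = 0.036 for ATF4-linked genes and 0.0327 for the endoplasmic reticulum part). PSAT1 and STC2, chosen after their values were seen, rose by 0.47 and 0.46 with A07 and fell by 0.51 and 0.44 with B02. ATF4 itself, also chosen after its values were seen, had a log2 fold change of -0.13 with A07 and fell by 0.32 with B02.

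Other pregnancy-specific glycoprotein genes rose in the mean of both hairpins beside PSG4, all chosen after their values were seen: PSG9 by 0.92, PSG3 by 0.87, PSG1 by 0.68 and PSG6 by 0.61. The dim genes PSG2 and PSG11 had log2 fold changes of 0.31 and 0.15 and did not pass. These genes are near-identical, so their probe sets are not independent measurements.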
